A study of Trichodesmium erythraeum IMS101 with 4 samples.

How the data were processed

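The data are RNA sequencing libraries of Trichodesmium erythraeum IMS101, a filamentous marine cyanobacterium that fixes nitrogen. Per the labels' protocols, cultures were kept in Aquil, a defined seawater medium, without added fixed nitrogen. RNA was collected on filters in the middle of the light period, depleted of ribosomal RNA, made into strand-specific libraries and read as single 50 bp reads. Bowtie2 2.2.6, a read aligner, is the tool named in the submitters' processing notes. The counting program, its strand setting, the genome build, the annotation version and the treatment of reads that map to several places are not given in the sources used here.

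The deposited table holds the authors' raw read counts per gene, 1 column for each of the 4 libraries and 4615 gene IDs, with no normalisation. Every column was used and every row names a gene. Total counts were 22897985 and 32159356 in the 2 libraries at 380 µatm CO2 and 31102456 and 29782226 in the 2 libraries at 750 µatm CO2. At these totals 3 counts, the limit used for a gene with no count, correspond to 0.0933 to 0.131 CPM, the usual normalised count scaled to a fixed library total. None of the IDs matched to the reference is annotated as ribosomal or transfer RNA, and the type of the 633 unmatched IDs is not known, so residual ribosomal RNA was not measured. All IDs are T. erythraeum locus tags, so no markers of other organisms were tested.

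Gene symbols came from a RefSeq table of the IMS101 assembly ASM1426v1, matched on old locus tags. 3982 of the 4615 IDs matched and 613 of them carry a symbol. That table gives no protein product names, so the gene lists, written as patterns on symbols and products, were matched on symbols alone. Of the 26 lists, 5 had no member matched by symbol, namely carbon concentrating mechanism, DNA methylation and restriction, caspase-like proteases, ribosomal RNA and transfer RNA. Genes of these kinds may be among the counted IDs without a symbol. A further 6 lists had 1 to 4 tested members, and the remaining 15 were tested as sets. No coordinates are given because the build used for counting is not stated. Reads of genes that share a symbol (such as the psbA and gvpA copies) could have been split between copies during counting, so their separate values are uncertain. Whether counts separate a gene from an antisense transcript is also not known.

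Libraries were grouped by the CO2 level in the labels. The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (4523 genes kept, 92 left out), TMM factors, and the quasi-likelihood test (glmQLFit and glmQLFTest, package defaults) with the group as the only term and Benjamini-Hochberg adjustment, called at an adjusted p of 0.05. CPM were computed from the deposited counts with the same factors. Standard errors of log2 fold changes were derived from the F statistic. All values of a gene are means of 2 libraries with their SD. The labels do not say that the libraries of a level came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No replicate pair agreed within sampling noise, since a chi-square statistic per degree of freedom over genes was 294 at 380 µatm and 111 at 750 µatm. The edgeR fit gave a common biological coefficient of variation of 16.4%. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.33, so shares of counts are given without a test. Wilson 95% intervals of shares cover counting error only.

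Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Both rest on the 2 residual degrees of freedom of this design, so they can hardly call any list. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. The rules for lists, tests and named genes were written before the data were examined. The named genes were to be those past the threshold. Because none passed, the rule took in each direction the 10 genes with the smallest p, the requirement of a symbol being kept, among genes with a mean of at least 10 CPM whose 2 groups do not overlap, with 2 genes without a symbol. It added the most abundant member of each list with at least 3 tested members and the 10 most abundant genes. A gene named by several parts counts under each. The rule's part on cytosine methyltransferases found no symbol. nifH, kaiB, kaiC, tpiA, rplU, gvpJ Tery_2323 and gvpN Tery_2329 were named after their values were seen. So were the genes of lists with 1 or 2 members, glpX, metK, ahcY and ltrA.

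The procedure was tested on counts simulated for this comparison from the means, dispersions and library sizes of the 4523 tested genes, with 200 changed genes in each of 5 runs. The edgeR test recovered 11% of 1.5-fold, 60.3% of 2-fold and 97.9% of 4-fold changes, with 7.6 false calls per run. DESeq2 1.42.0 recovered 74% of the 2-fold changes with 17.4 false calls per run, limma-voom 59.1% with 7.4, and edgeR with a replicate block 74.6% with 20. Simulated genes were drawn independently, with no effect shared by neighbouring genes or by libraries of the same number. These rates may therefore not hold for the real libraries. The alternatives tried were other scalings (DESeq2 size factors, total counts, upper quartile), DESeq2, limma-voom, no filter, a filter of at least 50 counts in 2 libraries, the replicate number as a block, a minimum fold change of 1.5, each library left out, and, for the lists, the estimated correlation and fry. Leaving out ribosomal and transfer RNA was planned but had nothing to remove. A robust quasi-likelihood fit, the edgeR 4 style fit and the removal of the 10 most abundant genes were added after seeing the data.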

Results

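The transcriptome of Trichodesmium erythraeum IMS101 was measured at 2 levels of CO2. Cultures were kept at 380 µatm CO2 (2 libraries) or were moved from 380 to 750 µatm and acclimated for 2 weeks, about 5 generations, before sampling (2 libraries). The study examined how the transcriptome and the cytosine methylome relate at the 2 levels, and the RNA counts are the part analysed here. The libraries held 22897985 to 32159356 gene counts in total, and 4602 to 4612 of the 4615 genes had at least 1 count in each library. The median count per gene was 858 to 1090. Libraries of the same level had a Pearson correlation of 0.991 in log2 CPM across genes at both levels, and libraries of different levels had correlations of 0.982 to 0.989. Genes are not independent replicates. The first principal component held 52.1% of the variance and separated the levels, with values of -15.57 and -7.49 at 380 µatm and 5.75 and 17.31 at 750 µatm. The second held 31.3% and followed the replicate number. Its values at 380 and 750 µatm were 6.94 and 10.77 in replicates 1 and -14.23 and -3.49 in replicates 2. On the first component, too, replicate 1 lay below replicate 2 at both levels.

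By mean CPM over the 4 libraries, photosynthesis and gas vesicle genes were among the most abundant. The 2 gvpA genes ranked 37 and 43 in replicate 1 at 380 µatm, 6 and 9 in replicate 2, and between 1 and 3 in the libraries at 750 µatm. Each library's own 10 most abundant genes took 17.3% to 18.3% of its counts. The 10 genes with the highest mean CPM over the 4 libraries included 3 genes named psbA, whose separate values are uncertain because reads could be split between copies, the D1 reaction centre protein of photosystem II, with Tery_4763 at 27960 ± 1147 CPM (SD, n = 2) at 380 µatm and 28140 ± 3454 at 750 µatm, a log2 fold change of 0.01 that was -0.02 with total-count scaling. The copy Tery_0182 stood at 16360 ± 2249 and 12980 ± 817 CPM, and the copy Tery_0183 at 14850 ± 1900 and 11670 ± 683 CPM. The photosystem I reaction centre genes psaA and psaB had 24610 ± 1667 and 23370 ± 777 CPM at 380 µatm and 19250 ± 1049 and 17690 ± 1142 at 750 µatm. Their log2 fold changes of -0.35 ± 0.20 (SE) and -0.40 ± 0.20 did not pass edgeR's quasi-likelihood test (adjusted p = 0.457 and 0.402). The others were both gvpA copies, psbB, which encodes a core antenna of photosystem II, and 2 genes without a symbol, Tery_4410 and Tery_0397. The log2 fold changes of these last 3 were -0.10, -0.14 and -0.18, with SEs of 0.21 to 0.24. Photosystem II genes with a symbol took 9.69% ± 0.386 of counts at 380 µatm and 8.78% ± 0.158 at 750 µatm. Photosystem I genes took 5.11% ± 0.630 and 3.94% ± 0.0628 (n = 2 each).

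At the level of single genes, no transcript passed the test between 750 and 380 µatm CO2. The edgeR quasi-likelihood test called 0 of 4523 genes higher and 0 lower after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.0997. At an unadjusted p under 0.05, 397 genes were higher and 288 lower, where 226 are expected by chance. With upper-quartile scaling these became 507 and 191, and without replicate 2 at 750 µatm 170 and 143. Limma-voom called 0 genes (681 at an unadjusted p under 0.05). DESeq2 called 157, of which 91 were higher and 66 lower at 750 µatm (610 at an unadjusted p under 0.05). Set between replicates 1 and replicates 2 of both levels, DESeq2 called 48 genes. Without replicate 2 at 380 µatm edgeR called 15 genes higher and 11 lower, and without replicate 1 at 750 µatm it called 1 higher. The 2 groups did not overlap for 46.6% of the genes, where chance gives 33.3%. The chance values of 226 genes and 33.3% are averages, and a single split of correlated genes can depart from them. By edgeR, replicates 1 against replicates 2 of both levels gave 338 genes at an unadjusted p under 0.05, and the crossed split gave 47. The median SE of a log2 fold change was 0.18, and 91 genes had a log2 fold change beyond 1 in either direction, 62 higher and 29 lower.

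None of the 10 genes with a symbol and the smallest p on the higher side passed edgeR's test. infC, which encodes translation initiation factor IF-3, had 284 ± 2.38 CPM at 380 µatm and 510 ± 53.1 at 750 µatm, a log2 fold change of 0.85 ± 0.15 (SE). psb35 and psb34, which carry photosystem II names, stood at 75.3 ± 7.42 and 153 ± 37.7 CPM at 380 µatm and at 132 ± 3.31 and 303 ± 67.4 at 750 µatm, log2 fold changes of 0.81 ± 0.14 and 0.98 ± 0.23. The lipA copy Tery_3493, for lipoyl synthase, had a log2 fold change of 0.77 ± 0.14, and the clpS copy Tery_3811, for an adaptor of the Clp protease, of 0.88 ± 0.18. rimP, for a ribosome maturation factor, and rpsN, for ribosomal protein S14, had 0.51 ± 0.13 and 0.53 ± 0.14, and cobI, of cobalamin synthesis, had 0.67 ± 0.18. The gas vesicle genes gvpJ Tery_2322 and gvpN Tery_2334 complete the 10 genes. Tery_4625 and Tery_2382, which have no symbol, had the smallest p of all genes, with log2 fold changes of 1.26 ± 0.13 and 1.47 ± 0.15. Adjusted p by edgeR ran from 0.0997 for these 2 genes to 0.208 for cobI. DESeq2 called at least infC, lipA Tery_3493 and psb35 (adjusted p = 0.000671, 0.000905 and 0.00215). It also called Tery_2382 and Tery_4625, with far smaller values (adjusted p = 2.716e-10 and 1.783e-09 by DESeq2).

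On the lower side, too, none of the 10 genes with a symbol and the smallest p passed edgeR's test. gap, for glyceraldehyde-3-phosphate dehydrogenase, had 32.2 ± 7.19 CPM at 380 µatm and 14.4 ± 0.203 at 750 µatm, a log2 fold change of -1.16 ± 0.20 (SE). fbp, for fructose bisphosphatase, had 156 ± 17.6 and 93.4 ± 6.88 CPM (-0.74 ± 0.15), and pyk, for pyruvate kinase, had -0.66 ± 0.18. thiC, of thiamine synthesis, had 264 ± 40.1 and 141 ± 3.88 CPM (-0.91 ± 0.16). metE, the cobalamin-independent methionine synthase, was the most abundant of these 10 genes at 6059 ± 1397 and 3284 ± 350 CPM (-0.88 ± 0.23). thrB, of threonine synthesis, trpC, of tryptophan synthesis, and purH, of purine synthesis, had -0.54 ± 0.15, -0.62 ± 0.16 and -0.73 ± 0.18. topA, for DNA topoisomerase I, had -0.54 ± 0.14, and the phosphonate-binding gene phnD Tery_4993 had -0.76 ± 0.22. The genes without a symbol were Tery_0846 and Tery_0841, at -1.02 ± 0.13 and -1.16 ± 0.16, and both lie with metE in 1 stretch of neighbouring locus tags. Adjusted p by edgeR ran from 0.134 to 0.22. DESeq2 called at least gap and thiC (adjusted p = 0.000318 and 0.000778). It also called Tery_0846 and Tery_0841 (adjusted p = 1.358e-05 each by DESeq2).

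**Figure D1:**
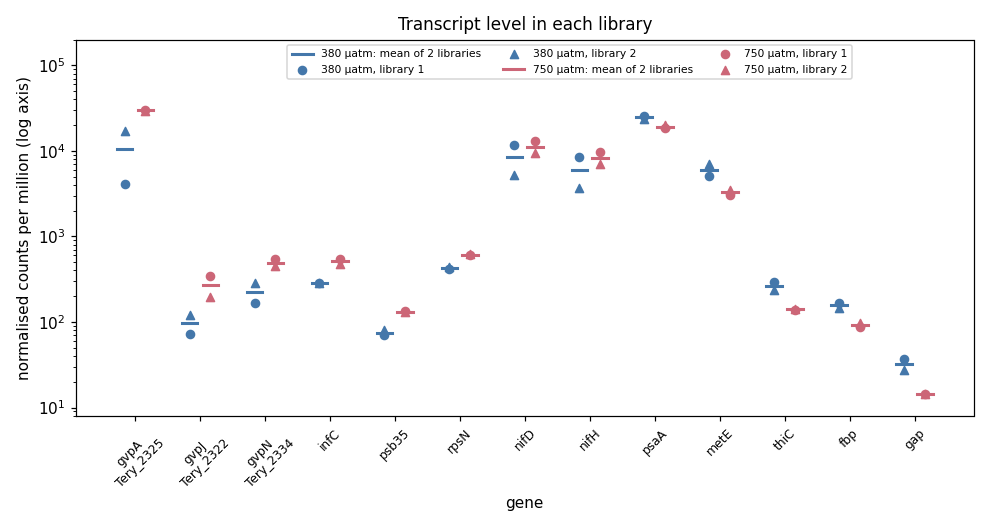
Normalised counts (CPM, log axis) of 13 genes in each library, circles and triangles marking libraries 1 and 2 and horizontal bars the mean of the 2 libraries at 380 µatm (blue) and 750 µatm (red). The libraries at 380 µatm lie far apart for gvpA Tery_2325, nifD and nifH, and close together for infC at a mean of 284 CPM.

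Gas vesicle genes, which encode the protein-walled buoyancy structures of planktonic cyanobacteria, rose as a list at 750 µatm by camera with a preset correlation (limma, adjusted p = 0.000351), a call lost with an estimated correlation (adjusted p = 0.832) and with fry (adjusted p = 0.697). All 6 members matched by symbol had positive log2 fold changes, at least 0.99 with a median of 1.44, and their locus tags lie close together. By edgeR 0 of the 6 passed over all genes tested, while DESeq2 called 4 of them higher. By edgeR 4, both gvpJ and both gvpN genes, were higher when adjusted over the list alone. gvpA Tery_2325, for the main shell protein, had 10630 ± 9246 CPM at 380 µatm and 29780 ± 234 at 750 µatm, and gvpA Tery_2324 had 9022 ± 7970 and 25510 ± 844. gvpJ Tery_2322 had 96.5 ± 32.9 and 271 ± 103 CPM, and gvpN Tery_2334 had 227 ± 86.0 and 496 ± 66.3. gvpJ Tery_2323 and gvpN Tery_2329 had log2 fold changes of 1.40 ± 0.40 and 0.99 ± 0.30 (SE). The libraries at 380 µatm lay far apart: the list took 0.883% of counts in replicate 1 at 380 µatm (Wilson 95% interval 0.879% to 0.886%), 3.20% in replicate 2 (3.20% to 3.21%), 5.97% in replicate 1 at 750 µatm (5.96% to 5.98%) and 5.495% in replicate 2 (5.487% to 5.5034%). The list's median log2 fold change was 0.80 without replicate 1 at 380 µatm and 1.99 without replicate 2 at 380 µatm. For gvpA Tery_2325 the values were 0.80 and 2.85. The preset correlation of 0.01 treats these genes as nearly independent, while the estimated correlation of the list was 0.888. With an estimated correlation camera also rests on only 2 residual degrees of freedom, as does fry. Either could hardly call any list here, so the lost call does not decide whether the list rose.

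Ribosomal protein genes as a list passed camera on the higher side with a preset correlation (limma, adjusted p = 0.00351). They did not pass with an estimated correlation (adjusted p = 0.832) or with fry (adjusted p = 0.79), which on 2 residual degrees of freedom could hardly call any list. Of 25 tested members 23 had positive log2 fold changes, with a median of 0.25 and a range of -0.28 to 0.54, and 0 passed over all genes or adjusted over the list alone. rplU, for ribosomal protein L21, had 300.3 ± 54.8 CPM at 380 µatm and 436 ± 8.96 at 750 µatm. The most abundant member, rplL, had 1427 ± 393 and 1684 ± 233 CPM. The call also ended without replicate 1 at 380 µatm (median 0.03, adjusted p = 0.684 by camera) and without replicate 2 at 750 µatm (median 0.16, adjusted p = 0.0758), and the median was 0.56 without replicate 2 at 380 µatm.

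Nitrogen fixation genes did not pass in either direction. Of 8 members 6 had positive log2 fold changes (median 0.26, range -0.37 to 0.58), and 0 were called over all genes or adjusted over the list alone (camera adjusted p = 0.326). nifH, for the nitrogenase iron protein, had 6066 ± 3342 CPM at 380 µatm and 8318 ± 1804 at 750 µatm. nifD, for a subunit of the molybdenum-iron protein, had 8464 ± 4570 and 11210 ± 2425 CPM, a log2 fold change of 0.41 with a 95% interval of -0.55 to 1.36. The list took 3.67% (Wilson 95% interval 3.66% to 3.68%) and 1.48% (1.47% to 1.48%) of counts in the 2 libraries at 380 µatm, and 3.74% (3.74% to 3.75%) and 2.66% (2.65% to 2.66%) in those at 750 µatm. Camera called the list higher without replicate 1 at 380 µatm (median 0.96, adjusted p = 6.7e-06), and the median was -0.20 without replicate 2 (adjusted p = 0.115). These values use the preset correlation, and over all 4 libraries camera with an estimated correlation gave adjusted p = 0.832.

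In the Calvin cycle list, gap and fbp were lower by edgeR when adjusted over the list alone, and 0 of 9 members passed edgeR over all genes. DESeq2 called 2 of the 9 lower over all genes. Both gap and fbp had mean CPM of 156 or less, while the member glpX had 2611 ± 634 and 2643 ± 315 (log2 fold change 0.02). Members were matched by symbol, so whether these gap and fbp genes serve the Calvin cycle or other carbon metabolism was not tested. The 9 members matched by symbol include no gene of RuBisCO, the CO2-fixing enzyme. tpiA, for triose-phosphate isomerase, lay on the other side with 364 ± 68.3 and 522 ± 15.9 CPM, and fba, for fructose-bisphosphate aldolase, the most abundant member, had 4829 ± 1037 and 4914 ± 589. The list's median log2 fold change was 0.02 (0.00 with total-count scaling), its mean -0.16 and its camera direction lower (adjusted p = 0.452). The median was -0.23 without replicate 1 at 380 µatm and without replicate 2 at 750 µatm, and 0.11 with either of the others left out, where camera's direction was higher without replicate 2 at 380 µatm. In central carbon and glycogen metabolism 11 of 15 members had negative log2 fold changes (median -0.20, camera adjusted p = 0.11), and camera called that list lower without replicate 2 at 750 µatm (adjusted p = 0.00326) but not without replicate 1 (median -0.07, adjusted p = 0.561). Over all 4 libraries an estimated correlation gave adjusted p = 0.832. Its most abundant member, gnd, for phosphogluconate dehydrogenase, had 1310 ± 568 and 1183 ± 113 CPM. kaiB and kaiC, the circadian clock genes matched by symbol, have adjacent locus tags. Both were lower by edgeR when adjusted over this list of 2 alone, which is little adjustment. Neither passed edgeR over all genes (adjusted p = 0.273 and 0.318). kaiB and kaiC had 49.8 ± 12.7 and 246 ± 25.4 CPM at 380 µatm and 30.1 ± 7.37 and 184 ± 30.4 at 750 µatm.

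Photosystem II had 15 of 21 members with positive log2 fold changes (median 0.13, camera adjusted p = 0.272), and psb35 alone passed when adjusted over the list alone. The photosystem I list of 6 had a median of 0.08 (adjusted p = 0.959), with psaA and psaB negative, and camera's direction turned to lower without replicate 2 at 380 µatm (median 0.04). The 3 phycobilisome genes matched by symbol, which encode light-harvesting antenna proteins, had -0.15 to -0.10, with cpcA at 8035 ± 949 and 7511 ± 474 CPM. In chlorophyll and tetrapyrrole synthesis 8 of 10 members were negative (median -0.22, adjusted p = 0.144). hemW had the lowest value, -0.78 ± 0.28 (SE), but is in the list by its symbol alone. Whether it acts in this synthesis was not examined. Electron transport genes had a median of -0.14 (adjusted p = 0.53), with petB, for cytochrome b6, at 5649 ± 299 and 5137 ± 327 CPM. ATP synthase genes had a median of -0.15 (adjusted p = 0.452), with atpB at 6220 ± 473 and 5718 ± 468 CPM. Their median was 0.07 without replicate 2 at 380 µatm, where camera's direction was higher, -0.01 without replicate 1 at 750 µatm, -0.30 without replicate 1 at 380 µatm and -0.25 without replicate 2 at 750 µatm. All adjusted p here are camera's, and 0 members of these lists passed edgeR over all genes. DESeq2 called 2 photosystem II genes higher over all genes.

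No member of the remaining lists passed edgeR over all genes, and no list among them passed camera. Over all genes DESeq2 called 1 gene higher among chaperones and proteases and 1 among translation factors. Nitrogen assimilation and transport had a median log2 fold change of -0.17 over 9 genes (adjusted p = 0.204), with glnA, for glutamine synthetase, at 1580 ± 153 and 1316 ± 374 CPM. Phosphorus acquisition had -0.11 over 14 genes (adjusted p = 0.11), with the phosphate-binding gene pstS Tery_3534 at 439 ± 46.2 and 474 ± 33.1 CPM. Chaperones and proteases had 0.00 over 21 genes (-0.02 with total-count and 0.06 with upper-quartile scaling, adjusted p = 0.723), with the chaperonin gene groL Tery_4327 at 8559 ± 3233 and 6231 ± 1883 CPM. Without replicate 2 at 380 µatm camera called photosystem II and chaperones higher and phosphorus acquisition lower, each at an adjusted p of 0.0288. With each of the other 3 libraries left out none of these 3 lists passed. The chaperone median was -0.14 without replicate 1 at 380 µatm and without replicate 2 at 750 µatm, and camera's direction for photosystem II was lower without replicate 1 at 380 µatm (median 0.04, adjusted p = 0.883). Over all 4 libraries an estimated correlation gave camera adjusted p = 0.832 for photosystem II and phosphorus acquisition and 0.96 for chaperones. Oxidative stress defence had -0.07 over 8 genes (adjusted p = 0.489), with the superoxide dismutase gene sodN at 2009 ± 587 and 1928 ± 175 CPM, and camera's direction turned to higher without replicate 2 at 380 µatm (median -0.03). Translation factors had -0.02 over 6 genes (0.04 with upper-quartile scaling) with a mean of 0.12 (camera direction higher, adjusted p = 0.576), infC being the 1 gene that passed adjusted over the list alone, and the elongation factor gene fusA Tery_0475 stood at 2973 ± 489 and 2890 ± 134 CPM (log2 fold change -0.04, and 0.02 with upper-quartile scaling). The translation median was -0.19 without replicate 1 at 380 µatm, where camera's direction was lower, 0.17 without replicate 2 at 380 µatm and 0.02 without replicate 1 at 750 µatm. The 4 iron metabolism genes matched by symbol had -0.65 to 0.08, with sufB at 166 ± 0.890 and 175 ± 54.5 CPM. The sigma factor genes matched by symbol, sigC and rpoD, had -0.20 and -0.30. The only transposase gene matched by symbol, tnpA, had -0.50 at 1.55 and 1.09 CPM. The only symbol that met the pattern of the toxin-antitoxin list, mazG, had -0.08.

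**Figure D2:**
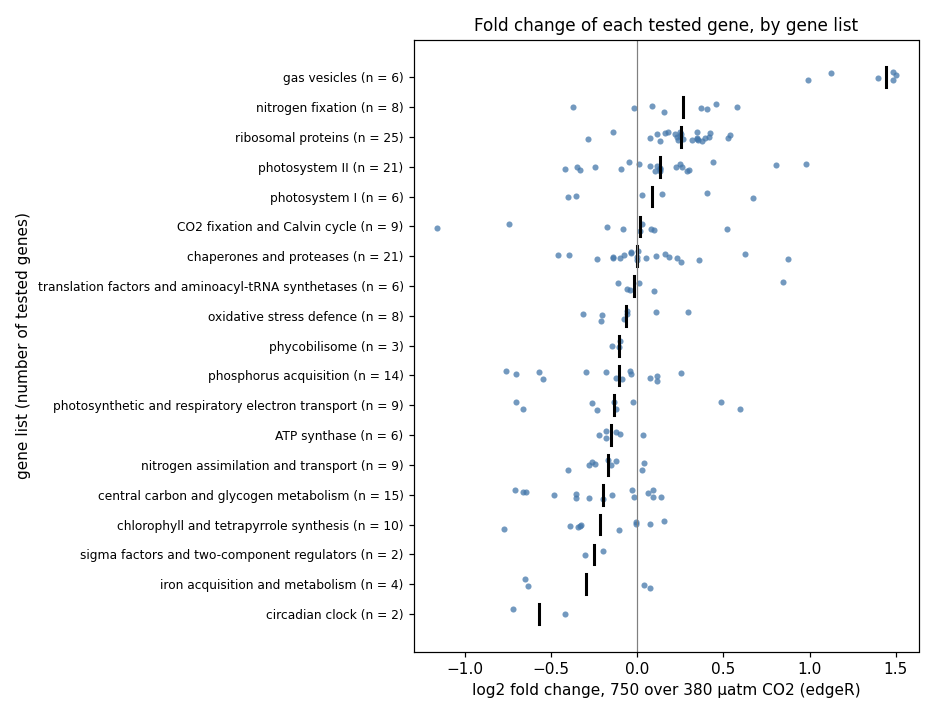
Log2 fold change (750 over 380 µatm CO2, edgeR) of each tested gene, 1 point per gene, by gene list, with the list's median as a black bar. The 6 gas vesicle genes lie at 0.99 or above, and the medians of the other lists between -0.57 and 0.26.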

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

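No gene was called by edgeR under the 3 other scalings, both other filters, limma-voom, a minimum fold change of 1.5, or the 3 fits added after seeing the data (robust quasi-likelihood, edgeR 4 style, without the 10 most abundant genes). The smallest adjusted p in these fits lay between 0.0508 with upper-quartile scaling and 0.406 with the minimum fold. DESeq2 called 91 genes higher and 66 lower. With the replicate number as a block, edgeR called 195 higher and 114 lower, and 156 of DESeq2's 157 genes were among them. The labels do not say that a number marks a shared culture or day. Same-numbered libraries deviated together (correlation 0.33 across 4523 genes), but with 2 numbers this does not establish a pairing, and the block leaves few degrees of freedom. It changed no list call. With 1 library left out, 0 to 15 genes were called higher and 0 to 11 lower; the 15 and 11 came without replicate 2 at 380 µatm, and 1 higher gene without replicate 1 at 750 µatm. Where an arm has 1 library, it is assumed to vary like the other arm. The lists called higher numbered 1 to 4 and those lower 0 to 1. Camera with an estimated correlation and fry each called 0 lists, while the other scalings, filters and the block kept gas vesicles and ribosomal proteins. The camera settings differ in the inter-gene correlation, preset at 0.01 and estimated at 0.888 for gas vesicles and 0.790 for ribosomal proteins. They also differ in degrees of freedom, since the estimated setting rests on the 2 residual ones. Nitrogen assimilation and transport, with an estimated correlation of -0.0856, still went from p = 0.0817 to 0.212 by camera. How much each of these accounts for the lost calls was not tested. The cause of the other differences was not tested. Over 16 alternatives, 12 of 55 named genes changed sign in 19 cases, 17 of them with 1 library left out, and none of these values was called. With 1 library left out, nifD ran from -0.07 to 1.10, nifH from -0.03 to 1.17 and rplL from -0.01 to 0.54. The other 9 genes lay within 1 SE of 0 with all libraries: gnd ran from -0.55 to 0.38, sodN from -0.33 to 0.26, sufB from -0.28 to 0.36, fba from -0.18 to 0.25, fusA Tery_0475 from -0.20 to 0.13, Tery_4410 from -0.36 to 0.10, psbA Tery_4763 from -0.12 to 0.13, cpcA from -0.21 to 0.02 and psbB from -0.22 to 0.02. The remaining 2 cases were psbA Tery_4763 at -0.02 with total counts and fusA Tery_0475 at 0.02 with the upper quartile. In 58 cases a named gene gained a call, 30 with the block, 19 with DESeq2 and 9 without replicate 2 at 380 µatm. Depth limited few of the named genes, the least counted being tnpA with 27 to 46 counts per library. Leaving out ribosomal and transfer RNA was not run, since no matched ID is annotated as either.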

Other observations

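The gene groups below and the tests of chance placement, of depth and of reads shared with copies were chosen only after the results they concern had been seen. Further gene groups with a symbol gave no called gene by edgeR (adjusted p under 0.05). Of 45 amino acid synthesis genes, 33 had negative log2 fold changes (median -0.09, camera adjusted p = 0.309 over 11 lists), and 10 had an unadjusted p under 0.05. Of 19 cell wall and division genes 16 were negative (median -0.20, adjusted p = 0.112). The methionine and S-adenosylmethionine cycle, which supplies the methyl group of DNA methylation, had 8 tested genes and a median of 0.13 (adjusted p = 0.925). Within it metK, for S-adenosylmethionine synthetase, had 6194 ± 1016 CPM (SD, n = 2) at 380 µatm and 6592 ± 278 at 750 µatm. ahcY, for adenosylhomocysteinase, had 7877 ± 3514 and 11290 ± 1824 CPM. Group II intron reverse transcriptases (6 ltrA genes) had a median of -0.07, and the copy Tery_3305 alone stood at 4922 ± 37.6 and 4506 ± 0.373 CPM. Hormogonium polysaccharide genes had a median of 0.00 over 9 genes, fatty acid and phospholipid synthesis -0.01 over 12, DNA replication and repair -0.08 over 27, purine and pyrimidine synthesis -0.09 over 17, hydrogenase maturation -0.13 over 5, lipid A synthesis -0.06 over 6 and thiamine synthesis -0.15 over 4.

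Genes with an unadjusted p under 0.05 lay next to each other in locus-tag order. Among 4111 adjacent tested pairs, 207 joined genes of the same direction, against a median of 48 and a highest value of 74 in 10000 random placements (share 1e-04, the smallest they can give), which argues against chance placement. Runs of at least 4 such genes included Tery_2325 to Tery_2329 and Tery_2331 to Tery_2334, in the gas vesicle region, with median log2 fold changes of 1.15 and 1.19. Tery_0810 to Tery_0816 had a median of 0.93, and Tery_2597 to Tery_2603 and Tery_3119 to Tery_3125 had -0.92 and -0.96. Neighbours may move together in any difference between libraries: their log2 differences correlated at 0.46 within 380 µatm and 0.41 within 750 µatm, against 0.51 between the levels. The gap to the level of 380 µatm is under the 0.1 set in advance, so co-transcription whatever the CO2 level cannot be told apart from a CO2 response.

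The 10 tested genes from Tery_0840 to Tery_0850, metE among them, had lower levels at 750 µatm, with log2 fold changes of -1.26 to -0.81 and a median of -1.03. None passed edgeR's adjusted threshold in the main fit, while DESeq2 called at least Tery_0841 and Tery_0846 (adjusted p = 1.358e-05 each). The median was -0.94 or lower with each library left out, and 100% of the genes lay under -0.5. The run was picked because its genes were lower with a small p, so these values decide neither on a single outlying library nor on reads shared with copies elsewhere, and both stay open. A candidate explanation is greater cobalamin synthesis, as metE is the cobalamin-independent enzyme, but the 19 cobalamin genes had a median of 0.02 (bootstrap 95% interval -0.16 to 0.07), with 10 above and 9 below 0. Members on both sides leave this open, as does a response to CO2, and DNA copy number of the segment was not analysed here.

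Libraries with the same replicate number deviated together from their group mean (correlation 0.33). Depth is argued against, since replicate 1 over replicate 2 in total counts was 0.71 at 380 µatm and 1.04 at 750 µatm. Noise of low-count genes is argued against by 0.36 among genes above the median CPM, and a trend with gene length by 0.31 after its removal (0.34 before, over 3934 genes with a length). A few operons are argued against by a median of 0.33 over 1000 draws of 1 gene per 10 locus tags with the gene lists left out. A shared sampling time or handling batch may remain, but the labels give none, so it stays untested. Of the 3 splits of the 4 libraries into 2 and 2, 1, the real one, gave 685 genes at an unadjusted p under 0.05 by edgeR, and the highest other, replicate 1 against replicate 2, gave 338. DESeq2 called 157 genes in the real split and 48 in that other one. These 3 splits are too few for a share under 0.05.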
